A study of Homo sapiens with 5 samples.

How the data were processed

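The series holds 5 single-channel Affymetrix human Gene 1.0 ST arrays of Nalm6 cells, 2 labelled as control and 3 as MLXIP knockout. Per the labels' protocols, cells grew in medium with 10% serum and 200 mg/dl glucose, virus was harvested 48 h after transfection of the producing cells, and 200 ng of total RNA per array was amplified and labelled with biotin. The number of guides against MLXIP, whether cells were cloned and whether the replicates are separate cultures are not given in the sources used here.

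The deposited values are intensity values per probe set made by the authors with RMA in Affymetrix Expression Console, per the submitters' processing notes, which give no version. RMA corrects the background, normalizes the arrays to each other by quantiles and summarises the probes of a probe set. The deposited table is on a linear scale: its values were all above 0, the array medians lay between 36.5 and 40.2 and the maxima between 16316 and 17305. The log2 of each value was taken before any test, as the design fixed beforehand had foreseen for a linear table. Because RMA forces similar distributions on the arrays, a change shared by most genes would be removed from these values. Each of the 5 columns was mapped to a labelled sample. No pair of arrays held identical columns, and the smallest median absolute log2 difference between 2 arrays was 0.112.

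Of 33297 probe sets, 19460 had exactly 1 gene symbol in the platform annotation used here, 1754 had several and 12083 had none. Of the 19460, 19429 probe sets had an Entrez identifier that matched the RefSeq table of assembly GRCh38.p14, through which 0 symbols changed. That table served only for names and for which genes neighbour each other. Probe sets with several symbols or none were not named. For the 769 symbols with several probe sets, the probe set with the highest mean over all 5 arrays was used, which left 18417 genes, with no filter on dim probe sets. Of the named genes, 9 had several probe sets, and in 1 of these, UHRF1, they differed in sign.

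The main test was limma (version 3.58.1 in R 4.3.3), with lmFit and eBayes with an intensity trend on all 5 arrays, MLXIP-KO minus control and no covariate. The two-sided p-values were adjusted by Benjamini and Hochberg over all genes, with a threshold of 0.05. Confidence intervals come from the same fit. The gene lists, 31 of pathways and 8 of cell type markers, were fixed before the data were examined, as were the tests and the rule for named genes. They hold 1006 entries, of which 913 were measured on a probe set with a single symbol. The other 93 were not analysed here. Lists were tested with camera at a preset correlation of 0.01, two-sided and adjusted over all 39 lists, with an estimated correlation and fry as alternatives. For members of a list, counts are given over all genes and adjusted over the list alone.

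The lists not described in the report gave the following. In the lysosome and autophagy list 1 of 31 genes rose and 2 fell (set adjusted p = 0.91, median 0.05 against a mean of -0.02). In the interferon response 1 of 30 fell (adjusted p = 0.85, median 0.04 against a mean of -0.01). In NF-kB and inflammatory response 1 of 22 rose and 1 fell (adjusted p = 0.76). Of 26 immediate early genes, 2 fell (adjusted p = 0.56). Of 23 adhesion, migration and niche receptor genes 2 rose and 4 fell (adjusted p = 0.21), and of 19 genes of the PI3K-AKT-FOXO axis 3 rose and 2 fell (adjusted p = 0.76). Adjusted over the list alone, higher and lower were 1 and 2 for lysosome, 0 and 1 for interferon, 1 and 1 for NF-kB, 1 and 2 for immediate early genes, 2 and 6 for adhesion, and 3 and 2 for PI3K. For PI3K fry pointed upwards while the median, mean and camera were below 0. The T and NK cell and mature B cell lists also had a median below 0 and a mean above 0.

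The rule for named genes took MLXIP, MLX, MLXIPL, TXNIP and ARRDC4 whatever their result, the 12 largest rises and 12 largest falls past the threshold with every MLXIP-KO array on the same side of both controls, and the 4 members with the smallest unadjusted p of each list. Symbols starting with LOC, LINC, OR, MIR, SNOR or RNU were left out of the largest changes. For the established cell line, chromosome Y genes are given as group values only. A group of 2 arrays is too small for a test of outlying arrays.

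The script was tested on simulated data with the real means and spreads of the 18417 genes in MLXIP-KO against control. It recovered 30% of 50 genes changed by 1.5-fold, 82% at 2-fold, and 94% at 3-fold and 4-fold, with 3.85% false among its calls. In simulated arrays with no list changed camera called 0 lists, and with 1 list raised by 0.5 on the log2 scale it called 1. These simulations do not decide which correlation between list members holds on the real arrays. There camera called 14 lists at the preset correlation and 0 with an estimated one. With so few arrays the test with an estimated correlation has little power, so its 0 calls do not decide this either.

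The alternatives tried were quantile normalization again, centring on the array median, a filter that left out the dimmest 25% (15384 genes left) or the dimmer 50% of probe sets (10705 left), the mean of a gene's probe sets, every probe set on its own, eBayes without trend or with robust estimation, array weights, the replicate number as a block, each array left out in turn, other thresholds, and a floor at the 10th percentile. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.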

Results

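Transcript levels were measured in Nalm6 cells, an established human B-cell precursor acute lymphoblastic leukaemia line, on Affymetrix human Gene 1.0 ST arrays. The series asks how MondoA, the protein encoded by MLXIP, relates to malignancy of this leukaemia and to its handling of metabolic stress. MondoA is a glucose-responsive transcription factor that binds DNA together with MLX. The cells carried Cas9 and either a scrambled guide RNA (control, 2 arrays) or a guide RNA against MLXIP (MLXIP-KO, 3 arrays), both delivered by lentivirus. The median signal of an array lay between 36.5 and 40.2 intensity units on the linear scale, and MLXIP-KO replicate 3 had the widest spread of values (SD 2.25 on the log2 scale, against 2.21 to 2.22 on the other arrays). Across genes, which are not independent replicates, the control arrays correlated with r = 0.995, the MLXIP-KO arrays with r = 0.991 to 0.993, and arrays of different groups with r = 0.978 to 0.984. The number of arrays limits the precision of every comparison.

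The comparison asks which transcripts differ once MLXIP is targeted, and MLXIP itself was lower on every MLXIP-KO array than on either control array. Its log2 level was 10.59 ± 0.10 (SD, n = 2) in control cells and 9.43 ± 0.09 (SD, n = 3) in MLXIP-KO cells, a fall of 2.23-fold (log2 change -1.15, 95% confidence interval -1.40 to -0.91, limma adjusted p = 1.7e-04). An exact two-sided permutation test of the 5 MLXIP values gave p = 0.1, the smallest that the 10 splits of 5 arrays allow. Where the guide cuts relative to the array's probes is not given in the sources used here, so the value describes the transcript and does not measure the protein or the edit. Its partner MLX was at 8.08 ± 0.03 (SD, n = 2) and 8.06 ± 0.10 (SD, n = 3), with an interval for the log2 change of -0.28 to 0.25. The paralog MLXIPL, which encodes ChREBP, had a log2 change of -0.10 with an interval of -0.40 to 0.20.

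**Figure D1:**
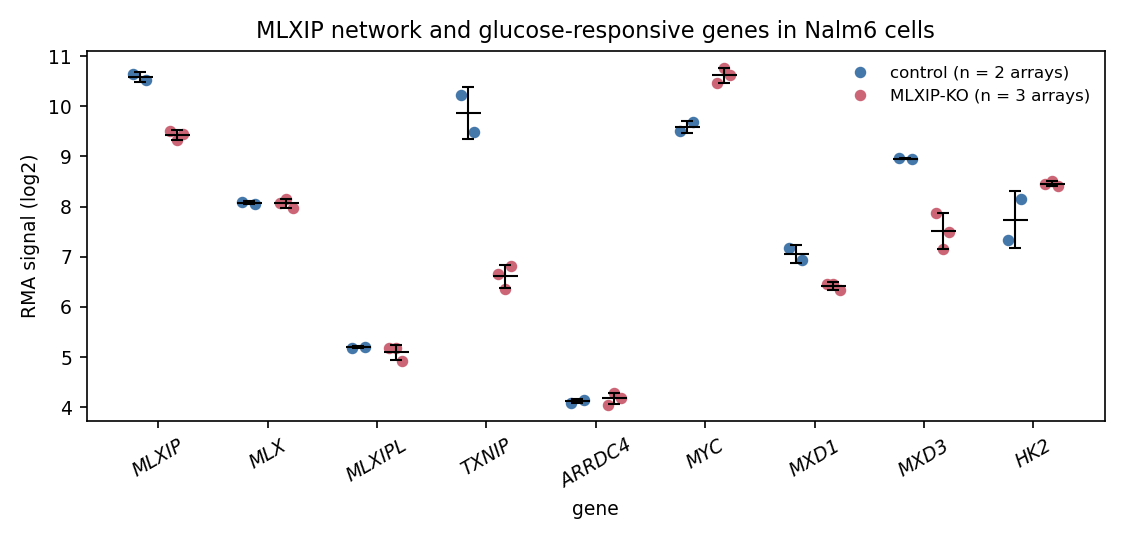
RMA signal (log2 of the deposited intensity, vertical axis) of 9 genes in control (2 arrays) and MLXIP-KO Nalm6 cells (3 arrays). Points are arrays, horizontal bars are group means and error bars are 1 SD. MLXIP and TXNIP lie lower on all 3 MLXIP-KO arrays, MYC lies higher, and MLX, MLXIPL and ARRDC4 overlap between the groups.

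The largest fall among known MondoA targets was that of TXNIP, an arrestin-like protein that limits glucose uptake, which fell 9.51-fold from a log2 level of 9.86 ± 0.52 (SD, n = 2) to 6.61 ± 0.23 (SD, n = 3). BHLHE40, a transcriptional repressor, fell by 1.62 on the log2 scale and ARRDC3, another arrestin-domain gene, fell by 0.65. HK2, which encodes a hexokinase, rose by 0.72. The remaining 14 of the 18 measured MondoA and ChREBP targets did not pass the test. ARRDC4 was among them (log2 change 0.06, 95% confidence interval -0.19 to 0.31). Its control log2 level of 4.12 lay at percentile 31.3 of the probe sets on the array. As a set the targets missed the threshold (median log2 change -0.08, limma camera adjusted p = 0.062). Adjusted over the list alone, 3 members fell and 1 rose, as over all genes. The set passed without control replicate 1 (median -0.14, adjusted p = 0.0035), as it did without MLXIP-KO replicate 1 (median -0.12, adjusted p = 0.038) and without the dimmer 50% of probe sets (adjusted p = 0.019). The HK2 call was lost without any single array other than control replicate 2, and without control replicate 1 its log2 change was 0.32 with an adjusted p of 0.45, against 1.12 without control replicate 2. The ARRDC3 call was lost without control replicate 2 (log2 change -0.53, adjusted p = 0.17).

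In the MYC-MAX-MLX network, MYC rose 2.03-fold while MXD3 and MXD1, which encode antagonists of MYC at shared DNA sites, fell by 1.45 and 0.63 on the log2 scale. Of the 13 measured members 1 rose and 4 fell, MLXIP included, with 2 higher and 4 lower adjusted over the list alone, and the set missed the threshold (camera adjusted p = 0.54). Without control replicate 1 the MXD1 change was -0.51 with an adjusted p of 0.22, and without control replicate 2 it was -0.75 with an adjusted p of 0.057.

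Over all genes, 1786 of 18417 differed between MLXIP-KO and control cells at an adjusted p below 0.05. Of these, 1148 were higher and 638 lower, with 183 higher and 154 lower by at least 2-fold. Without control replicate 1 the count was 569 and without control replicate 2 it was 654. On all 1786 the groups did not overlap, and the groups were separated for 41.0% of all genes tested, where chance gives 20%. Among the 12 largest rises were 6 genes of chromosome Y. EIF1AY, a translation initiation factor, rose 33.3-fold, the ribosomal protein gene RPS4Y1 26.3-fold, the RNA helicase gene DDX3Y 22.7-fold and UTY 11.4-fold, followed by USP9Y (7.43-fold) and TBL1Y (4.98-fold). In control cells the mean levels of these 6 genes lay at percentiles 15.4 (EIF1AY) to 42.6 (RPS4Y1) of the probe sets, below the array median. In MLXIP-KO cells they lay at percentiles 69.7 (USP9Y) to 94.3 (RPS4Y1). Of 23 measured chromosome Y genes 12 were called higher and 0 lower, with log2 changes of 0.58 to 5.06. The cells hybridised in the 2 groups thus differed in chromosome Y transcripts as well as in MLXIP. Without chromosome Y genes 1768 genes (1130 higher and 638 lower) and 14 gene lists were called, an alternative added after the data had been seen.

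The other large rises were PRKACB, a catalytic subunit of protein kinase A (6.66-fold), GSTP1, a glutathione transferase (5.75-fold), TTN (log2 change 2.49), TBCEL (5.39-fold), JCHAIN, the joining chain of secreted immunoglobulin (4.75-fold), and PTGER4, a prostaglandin E2 receptor (4.38-fold). The largest fall was that of the antisense transcript ZNF667-AS1, by 20.1-fold. The receptor tyrosine kinase genes KIT (14.5-fold) and PDGFRA (6.09-fold) fell, as did the microtubule-associated gene MAP1B (14.1-fold) and TFDP1, which encodes the dimerisation partner of E2F factors (log2 change -3.58). DEPP1, a target of FOXO factors, fell 8.68-fold, and further falls were those of CHRDL1 (7.80-fold), NRG3 (7.58-fold), ENPP2, which encodes autotaxin (6.72-fold), the inositol phosphate phosphatase gene MINPP1 (log2 change -2.58) and MFAP4 (5.90-fold). Of these genes PDGFRA varied most among the MLXIP-KO arrays (SD 1.38, n = 3). Its log2 change was -1.82 without MLXIP-KO replicate 2, against -2.61 on all arrays, and its call was lost in 4 alternatives: robust estimation (adjusted p = 0.24), every probe set on its own (0.10), and without control replicate 1 (0.057) or 2 (0.067). Without control replicate 1 or 2 the log2 change was -2.09 or -3.41 for ENPP2 (-2.75 on all arrays), and 1.86 or 3.11 for TTN. Of these 24 largest changes, 22 stayed past the threshold under every alternative in which they were tested, the exceptions being PDGFRA and ENPP2 (adjusted p = 0.071 with robust estimation). Of all 137 called genes that the naming rule took, 66 did. Some of the 24 largest changes had 1 group near the dim end of the array, where the 10th percentile was a log2 level of 3.1. In MLXIP-KO cells ZNF667-AS1 and MINPP1 were at 3.3 and 3.4. In control cells JCHAIN, PRKACB and TBCEL were at 3.4, 3.6 and 3.7. The chromosome Y genes EIF1AY, USP9Y and DDX3Y were at 3.3, 3.8 and 3.9 there. The fold sizes of these genes rest on such dim signals.

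**Figure D2:**
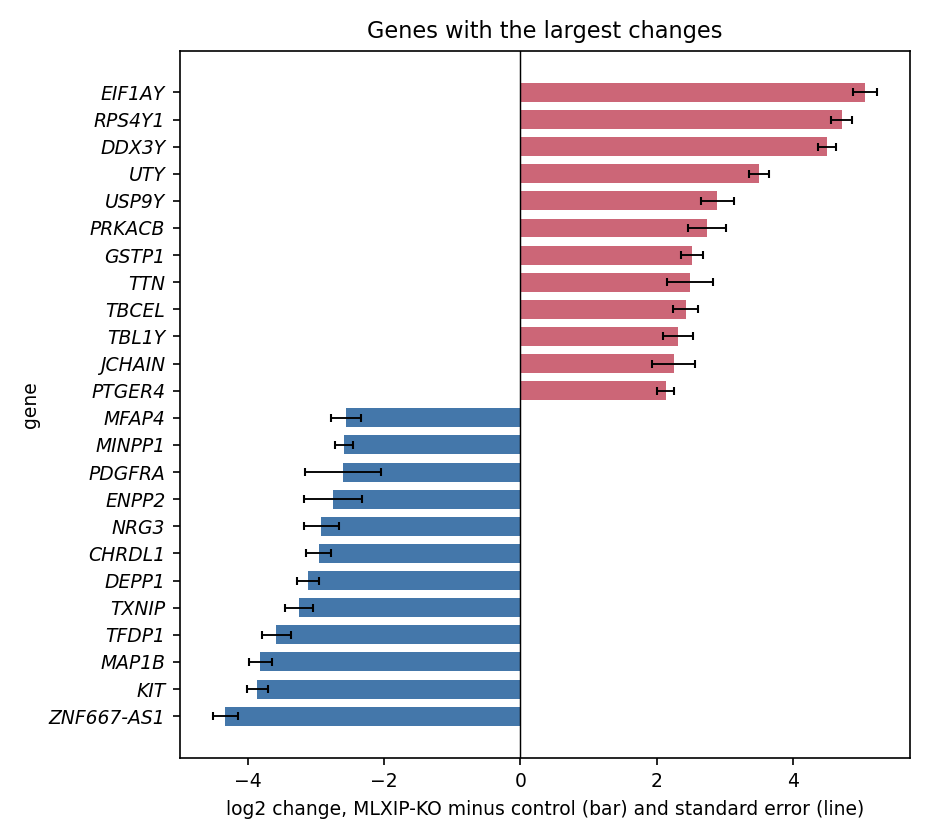
Log2 change from control (2 arrays) to MLXIP-KO (3 arrays) for the 12 largest rises and 12 largest falls (horizontal axis), 1 gene per row. Bars start at 0, lines are the standard error from limma, red bars are higher and blue bars lower in MLXIP-KO cells. The changes run from -4.33 for ZNF667-AS1 to 5.06 for EIF1AY.

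Genes for making ribosomes rose together, the strongest shift among the gene lists. Of 29 measured ribosome biogenesis genes 25 rose and 0 fell, with a median log2 change of 0.83 (camera adjusted p = 7.6e-22, adjusted p = 0.65 with an estimated correlation). RRP1B (2.55-fold), POLR1B, a subunit of RNA polymerase I (2.48-fold), WDR43 (2.46-fold) and the nucleolar helicase gene DDX21 (2.40-fold) had the smallest p-values. The count adjusted over the list alone was 26. In the list of cytosolic aminoacyl-tRNA synthetases and translation initiation factors 5 of 19 rose and 1 fell, with 6 higher and 2 lower adjusted over the list alone, among them EIF4G1 (log2 change 0.93) and VARS1 (1.02). That list missed the threshold (adjusted p = 0.056) but passed without control replicate 1 (adjusted p = 0.0042), without MLXIP-KO replicate 1 (adjusted p = 0.014) and with every probe set on its own (adjusted p = 0.0082).

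In the mitochondrial lists some genes rose, the list medians were smaller than for ribosome biogenesis, and most members did not pass. Of 31 measured genes of the mitochondrial ribosome and translation 11 rose and 0 fell (median 0.41, camera adjusted p = 2.7e-10, adjusted p = 0.65 with an estimated correlation), including MRPS2 (1.98-fold) and MRPL3 (1.67-fold). Of 51 oxidative phosphorylation genes 15 rose and 0 fell (median 0.24, adjusted p = 2.1e-07, adjusted p = 0.65 with an estimated correlation). ATP5MC1, a subunit of the ATP synthase rotor, rose 2.45-fold, CYC1, which encodes cytochrome c1, 1.73-fold and the complex I gene NDUFA2 1.54-fold. In the tricarboxylic acid cycle 5 of 20 genes rose, such as IDH3A (1.98-fold) and MDH2 (1.74-fold), and PCK2, the mitochondrial enzyme that makes phosphoenolpyruvate from oxaloacetate, fell 1.78-fold (median 0.19, adjusted p = 0.0086, adjusted p = 0.65 with an estimated correlation). For fatty acid oxidation 4 of 27 genes rose and 0 fell (median 0.16, adjusted p = 0.040, adjusted p = 0.65 with an estimated correlation), including ACAD9 (1.75-fold) and ECI2 (1.64-fold). Among 16 genes of the pyruvate dehydrogenase complex and its regulators the complex subunits DLAT (1.57-fold) and PDHA1 (1.48-fold) and pyruvate carboxylase, PC (1.65-fold), rose, while PDPR, a regulatory subunit of the phosphatase that activates the complex, fell 1.53-fold (set adjusted p = 0.25). Adjusted over the list alone, the counts were 16 higher for the mitochondrial ribosome, 19 for oxidative phosphorylation, 6 higher and 1 lower for the cycle, 4 higher for fatty acid oxidation, and 4 higher and 3 lower for the dehydrogenase list. Fatty acid oxidation missed the threshold in 7 of 17 alternatives, with an adjusted p of up to 0.21 (without the dimmer 50% of probe sets), without MLXIP-KO replicate 3 (0.14) and without control replicate 1 (0.094) among them. The cycle missed it in 3 of 17, with an adjusted p of up to 0.081, and without MLXIP-KO replicate 3 its median was 0.11 (adjusted p = 0.053). Among single genes, PC, DLAT, PDPR, PDHA1, PCK2, CYC1, NDUFA2, ACAD9 and ECI2 missed the threshold without control replicate 1 (adjusted p of 0.053 to 0.17). Without control replicate 2, DLAT, PDPR, PDHA1, IDH3A, NDUFA2, MRPL3 and ECI2 missed it (adjusted p of 0.059 to 0.17), and PDHA1 also without MLXIP-KO replicate 2 or 3 (adjusted p of 0.066 and 0.065).

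**Figure D3:**
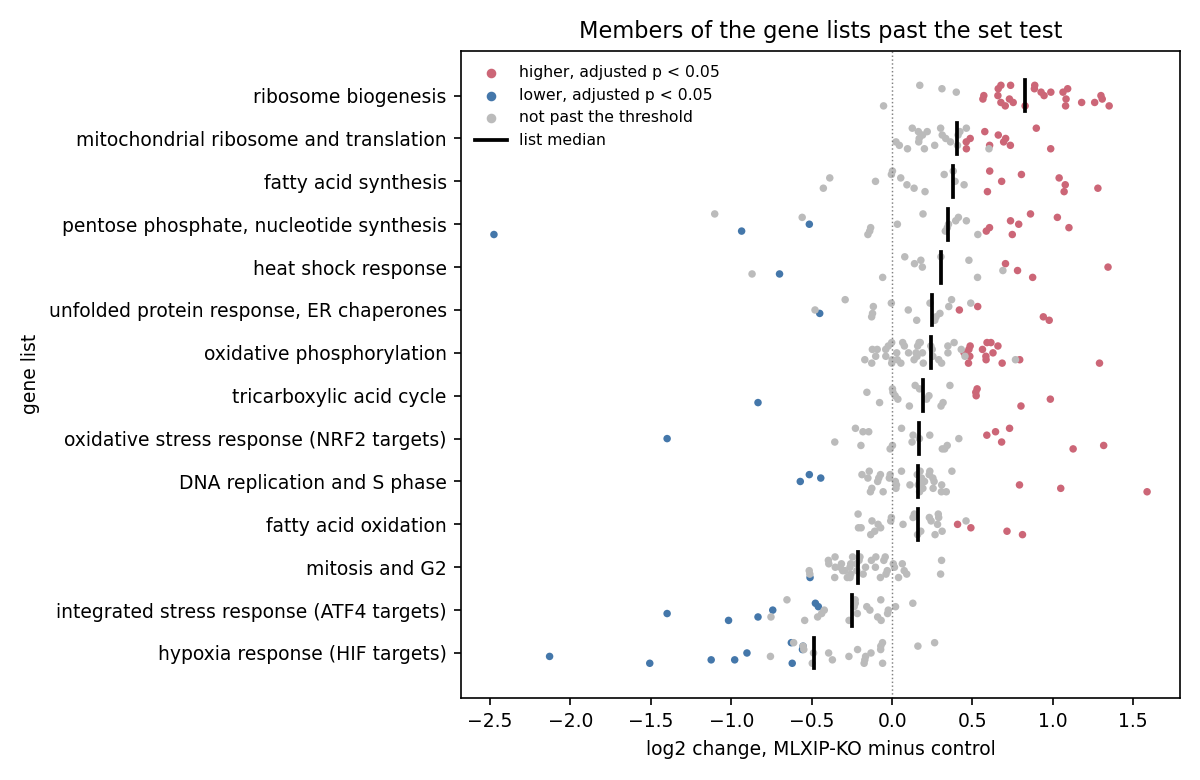
Log2 change from control (2 arrays) to MLXIP-KO (3 arrays) of each measured member (points, horizontal axis) of the 14 gene lists past the camera test with its preset correlation (rows, sorted by median). Red points rose and blue points fell at an adjusted p below 0.05, grey points did not pass, and black bars are list medians. Medians run from -0.49 for hypoxia response genes to 0.83 for ribosome biogenesis genes.

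In fatty acid synthesis and in cholesterol synthesis most genes did not pass, and those that did rose. Of 21 fatty acid synthesis genes 8 rose and 0 fell (median 0.38, camera adjusted p = 2.1e-05, adjusted p = 0.65 with an estimated correlation). FASN, the fatty acid synthase gene, rose 2.11-fold, the elongase gene ELOVL5 2.10-fold, LPIN1, which makes diacylglycerol, 2.43-fold, and ACLY, which makes cytosolic acetyl-CoA, 1.60-fold. In cholesterol synthesis and uptake 1 of 19 genes rose, DHCR7 by 1.53-fold (set adjusted p = 0.56). Among 25 genes of the pentose phosphate pathway and nucleotide synthesis 8 rose and 3 fell (median 0.35, adjusted p = 0.015, adjusted p = 0.89 with an estimated correlation). The purine synthesis genes ATIC (2.14-fold) and PPAT (1.73-fold) rose, whereas CTPS2, a CTP synthase, fell 5.56-fold and TKT, the transketolase of the pentose phosphate pathway, fell 1.91-fold. With p-values adjusted over the list alone, 10 rose and 1 fell for fatty acid synthesis, 14 rose and 4 fell for the nucleotide list, and 1 rose and 1 fell for cholesterol. The nucleotide list did not pass in 6 of 17 alternatives (adjusted p of up to 0.13), without control replicate 1 (0.078) and without MLXIP-KO replicate 3 (0.10) among them. DHCR7 missed the threshold without control replicate 1 or 2 (adjusted p of 0.085 and 0.11), and ACLY without control replicate 1 (adjusted p = 0.056).

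The glycolysis list missed the threshold as a set. Of 21 measured genes ENO2 (4.38-fold), TPI1 (1.77-fold) and the glucose transporter gene SLC2A3 (1.54-fold) fell and HK2 rose, with a set median of -0.14 and an adjusted p of 0.27. Its median without control replicate 1 was -0.46 with an adjusted p of 4.3e-06, and without control replicate 2 it was 0.03 with an adjusted p of 0.21. Genes of glutamine and amino acid metabolism went both ways, with 6 of 19 higher and 4 lower (set adjusted p = 0.39). ALDH18A1, the enzyme that starts proline synthesis from glutamate, rose 2.29-fold and ODC1, the rate-limiting enzyme of polyamine synthesis, 2.23-fold. In serine, glycine and one-carbon metabolism 3 of 16 rose and 1 fell (set adjusted p = 0.76). GLDC, of the glycine cleavage system, rose 2.90-fold and MTHFD2, an enzyme of mitochondrial folate metabolism, fell 1.37-fold. The median of that list was below 0 (-0.08) while its mean and test were above 0. Counts adjusted over the list alone were 2 higher and 3 lower for glycolysis, 7 and 4 for amino acids, and 4 and 2 for one-carbon metabolism. The SLC2A3 and MTHFD2 calls were lost without control replicate 1 and also without control replicate 2. Their log2 changes kept a similar size, at -0.75 to -0.49 and -0.52 to -0.39 over all alternatives, against -0.62 and -0.46 on all arrays. The sizes of HK2 and TPI1 moved more. The HK2 call was lost without control replicate 1, with a log2 change of 0.32 against 0.72 on all arrays. The TPI1 call was lost without control replicate 2, with a log2 change of -0.46 against -0.82 on all arrays. SLC2A3 also missed the threshold without MLXIP-KO replicate 2 (adjusted p = 0.066).

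Stress-response lists moved in different directions. Of 29 measured hypoxia response genes, targets of HIF factors, 9 fell and 0 rose (median -0.49, camera adjusted p = 2.1e-07, adjusted p = 0.65 with an estimated correlation), with 14 lower adjusted over the list alone. They included the collagen prolyl hydroxylase gene P4HA2 (2.84-fold), the growth factor gene VEGFA (2.18-fold), ENO2 and INSIG2 (1.87-fold), and 11 of the 29 members also stood in another list. Without control replicate 2 the hypoxia median was -0.17, still past the threshold (adjusted p = 0.0020), and INSIG2 was not (adjusted p = 0.078). In the integrated stress response, targets of ATF4, 6 of 26 fell and 0 rose (median -0.25, adjusted p = 1.6e-05, adjusted p = 0.65 with an estimated correlation). The cystine transporter gene SLC7A11 fell 2.64-fold, VLDLR 2.02-fold, PCK2 1.78-fold and ASNS, the asparagine synthetase gene, 1.67-fold. Without control replicate 1 that list had a median of -0.11 and an adjusted p of 0.076, and without control replicate 2 a median of -0.49 and an adjusted p of 4.3e-12. SLC7A11, PCK2 and ASNS missed the threshold without control replicate 1 (adjusted p of 0.11, 0.15 and 0.23), and 16 of the list's 26 members also stood in another list.

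The chaperone and antioxidant lists moved the other way. In the unfolded protein response 4 of 20 rose and 1 fell (median 0.25, camera adjusted p = 0.023, adjusted p = 0.65 with an estimated correlation), with the endoplasmic reticulum chaperones HSPA5 (1.97-fold) and HYOU1 (1.92-fold) higher and the transcription factor XBP1 1.37-fold lower. In the heat shock response 4 of 15 rose and 1 fell (median 0.30, adjusted p = 0.0086, adjusted p = 0.85 with an estimated correlation), for example HSPE1 (1.83-fold) and HSP90AB1 (1.72-fold). Without control replicate 2 neither list passed, with adjusted p-values of 0.25 and 0.43, and the heat shock median was 0.16 there against 0.49 without control replicate 1. The unfolded protein response missed the threshold in 6 of 17 alternatives, without MLXIP-KO replicate 3 (adjusted p = 0.053) among them. Without the dimmer 50% of probe sets heat shock and NRF2 targets missed it too (adjusted p of 0.069 and 0.081). Of 23 NRF2 targets 6 rose and 1 fell (median 0.17, adjusted p = 0.015, adjusted p = 0.65 with an estimated correlation). The thioredoxin gene TXN rose 2.49-fold and the superoxide dismutase gene SOD1 2.18-fold, while SLC7A11 fell. Adjusted over the list alone, the counts were 9 lower for the ATF4 targets, 5 higher and 1 lower for the unfolded protein response, 7 higher and 2 lower for heat shock, and 8 higher and 2 lower for NRF2 targets. XBP1, HSP90AB1 and SLC7A11 missed the threshold without control replicate 1 (adjusted p of 0.20, 0.092 and 0.11), and XBP1, HYOU1 and HSPE1 without control replicate 2 (adjusted p of 0.14, 0.079 and 0.054).

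Cell cycle and survival genes showed small or mixed changes. Of 40 mitosis and G2 genes 1 fell, SPC25 by 1.42-fold, and the median was -0.21 (camera adjusted p = 0.0055, adjusted p = 0.89 with an estimated correlation), with 0 called adjusted over the list alone. Without MLXIP-KO replicate 2 the median of that list was -0.09 with an adjusted p of 0.21. Among 41 DNA replication and S phase genes 3 rose and 3 fell (median 0.16, adjusted p = 0.043, adjusted p = 0.90 with an estimated correlation). The replication list did not pass in 10 of 17 alternatives, with an adjusted p of up to 0.37 (without control replicate 1). Among the others were quantile normalization (0.27), median centring (0.068), and the fits without the dimmer 50% of probe sets (0.32), MLXIP-KO replicate 1 (0.057) or MLXIP-KO replicate 3 (0.30). UHRF1, which maintains DNA methylation, rose from a log2 level of 8.51 to 10.10 on the probe set used, while its dimmer probe set had a log2 change of -0.01, RFC5 rose 2.07-fold and the licensing factor gene CDT1 fell 1.49-fold. Among 23 regulators of apoptosis 5 rose and 4 fell (set adjusted p = 0.85). The anti-apoptotic gene BCL2 rose 2.57-fold and its relative BCL2L1 fell 2.04-fold, while the pro-apoptotic genes BMF and BID had log2 changes of -0.83 and 0.71, both past the threshold. Of 26 p53 targets 4 rose and 4 fell (set adjusted p = 0.76), such as TP53INP1 (2.21-fold lower) and PLK3 (1.55-fold higher). Counts adjusted over the list alone were 3 higher and 3 lower for replication, 5 and 5 for apoptosis, and 4 and 5 for p53 targets. TP53INP1, PLK3, BMF, BID, CDT1 and SPC25 missed the threshold without control replicate 1 (adjusted p of 0.062 to 0.21), PLK3, CDT1 and SPC25 without control replicate 2 (0.080 to 0.34), and SPC25 without MLXIP-KO replicate 1 or 2 (0.090 and 0.097).

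Markers of early B cells changed in both directions. Of 27 pro-B and pre-B markers 4 rose and 6 fell (median -0.02, set adjusted p = 0.56). The inhibitory receptor gene CD22 rose 4.07-fold and IL7R, the receptor for interleukin 7, 2.73-fold, while the transcription factor gene BCL11A fell 3.80-fold and the recombinase gene RAG1 2.71-fold. Among 20 mature B cell markers BCL6, a repressor used in germinal centres, rose 3.80-fold and the MHC class II transactivator gene CIITA fell by 0.66 on the log2 scale (set adjusted p = 0.95). In antigen presentation 4 of 14 fell and 1 rose (median -0.43, set adjusted p = 0.064). The class II genes HLA-DPA1 (2.10-fold) and HLA-DPB1 (2.06-fold) fell and TAPBP, the tapasin gene, rose 1.60-fold. Without control replicate 2 the antigen presentation list passed (median -0.49, adjusted p = 0.010), as it did in 5 of 17 alternatives in all, without MLXIP-KO replicate 1 (adjusted p = 0.038) among them. Of 13 plasma cell markers JCHAIN rose, and XBP1 and TNFRSF17 (1.39-fold) fell (set adjusted p = 0.75). The median was -0.04 against a mean of 0.10. TNFRSF17 was dim, at a mean log2 level of 3.86 in control and 3.38 in MLXIP-KO cells. Counts adjusted over the list alone were 7 higher and 8 lower for pro-B and pre-B cells, 1 and 1 for mature B cells, 1 and 7 for antigen presentation, and 2 and 2 for plasma cells. XBP1, CIITA, HLA-DPB1, HLA-DPA1 and TNFRSF17 missed the threshold without control replicate 1 (adjusted p of 0.074 to 0.24), XBP1, TAPBP and CIITA without control replicate 2 (0.062 to 0.14), and TNFRSF17 without MLXIP-KO replicate 1 or 3 (0.065 and 0.077).

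Markers of other cell types showed no shared rise. Of 25 T and NK cell markers 2 rose, the transcription factor gene GATA3 by 2.54-fold and the kinase gene ZAP70 by 1.91-fold (set adjusted p = 0.79). Of 24 myeloid markers 1 rose, CD68 by 1.64-fold (set adjusted p = 0.80), and of 18 erythroid and megakaryocytic markers 1 rose, the transferrin receptor gene TFRC by 2.08-fold (set adjusted p = 0.74). Of 17 stem and progenitor markers KIT and FLT3 (1.68-fold) fell (set adjusted p = 0.062). The median of that list was -0.05 against a mean of -0.32, with KIT at a log2 change of -3.86. The stem and progenitor list passed without the dimmest 25% of probe sets (set adjusted p = 0.035). None of 16 markers of embryonic kidney and epithelial cells, the kind of line in which the virus was made, passed in limma, and the median was -0.13 (set adjusted p = 0.091, or 0.049 with camera on ranks). Adjusted over the list alone the counts were unchanged except that TFRC did not pass. ZAP70 and TFRC missed the threshold without control replicate 1 (adjusted p of 0.24 and 0.32), CD68 without control replicate 2 (0.23), and each of the 3 without MLXIP-KO replicate 3 (0.059 to 0.13). ZAP70 also missed it without control replicate 2 (0.050) or MLXIP-KO replicate 1 (0.070), and TFRC without MLXIP-KO replicate 2 (0.075).

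The gene lists were tested with limma camera at a preset correlation, which called 14 of 39 lists, 11 higher and 3 lower. With the correlation estimated from the data camera called 0 lists, and 0 had an unadjusted p below 0.05. The smallest unadjusted p in that test was 0.056. Ribosome biogenesis, with 25 of 29 genes higher, reached 0.10. With so few arrays the estimated-correlation test has few degrees of freedom and little power. Its p-values, those given above for single lists included, therefore neither back nor count against the calls at the preset correlation. Limma's fry, which asks whether a list's genes move one way on balance, also called 0, with 12 at an unadjusted p below 0.05. The labels do not say whether the arrays of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical. Centring each array on its median moved the split to 1137 higher and 389 lower (74.5% higher, against 64.3% in the deposited scaling).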

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

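The alternatives without chromosome Y genes and without the shifted stretch were chosen after seeing the data. MLXIP stayed past the threshold under all 18 alternatives run for it (log2 change -1.22 to -1.09, adjusted p 5.7e-05 to 0.0074). No gene or list that passed the threshold in either setting changed sign. Medians close to 0 did change sign in lists that passed neither on all arrays nor in the alternative. Examples were the MYC network, amino acid metabolism, p53 targets and immediate early genes. The glycolysis median ran from -0.46 without control replicate 1 to 0.03 without control replicate 2. With 1 control array left, the lone array is assumed to vary like the MLXIP-KO arrays. Without each array in turn the number of changed genes ran from 569 (without control replicate 1; 325 higher, 244 lower) through 654 (without control replicate 2; 398 higher, 256 lower) to 1765, with 325 to 1204 higher and 244 to 680 lower. Of the 569 and 654 genes, 544 and 629 were shared with the 1786. Fits with fewer arrays have less power, but not every count fell. Without MLXIP-KO replicate 1, 1204 genes were called higher, against 1148 on all arrays. Lists called ran from 9 (without MLXIP-KO replicate 3) to 16. Testing every probe set on its own called 882 probe sets (551 higher, 331 lower), with more tests to adjust for. Probe sets with a symbol covered 655 called genes, 652 of them shared with the 1786. The lower genes numbered 389 after median centring, which moved the median of all genes by 0.07, 960 with array weights (MLXIP-KO replicate 3 had weight 0.43) and 965 at an adjusted p below 0.10 (2598 in all). Without the dimmer 50% of probe sets 8 lists were called, and the cause was not tested. Camera with an estimated correlation called 0 lists, fry 0 and camera on ranks 15. Of the 14 lists, 5 stayed past the threshold under every alternative other than these set tests: ribosome biogenesis, mitochondrial ribosome, oxidative phosphorylation, fatty acid synthesis and hypoxia response. The other 9 missed it in 1 (ATF4 targets, mitosis and G2, NRF2 targets) to 10 (DNA replication) of 17 alternatives. All 14 kept their direction under both scalings.

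The replicate block used 2 shared numbers. MLXIP-KO replicate 3 has no control of its number and so did not enter the changes estimated with the block. The differences between replicates 1 and 2 correlated at -0.02 between the groups across genes, so the numbers were not taken to pair the arrays. With the block 2062 genes (1158 higher, 904 lower) and 10 lists were called, and MLXIP was at -1.17. Another background correction and slide or scan date as a block were not run, since the value table alone was used. Signal over background could not be measured per probe set here, so how far background compresses the changes of dim genes is not known here.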

Other observations

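The tests of exchanged arrays, of other-lineage cells and of signal level below, and the repeats without histone genes, were chosen only after related results were seen. Of 73 measured histone genes, a group chosen after its values were seen, 0 rose and 9 fell, with a median log2 change of -0.24 (-0.21 after quantile normalization and -0.17 after median centring). Of the 73, 48, dim ones included, lie in a single stretch described below. Many histone genes are nearly identical in sequence, and cross-hybridisation between them was not tested, so the members are not independent.

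Single members changed in 5 fixed lists that missed the threshold, those of adhesion, PI3K-AKT-FOXO, immediate early, NF-kB and lysosome genes. ICAM2 (2.01-fold) and ICAM3 (1.99-fold), which encode ligands of the integrin LFA-1, rose, while the chemokine receptor gene CXCR4 fell 1.56-fold. AKT1 rose by 1.00 on the log2 scale and AKT2 1.42-fold, and the cyclin gene CCNG2, a FOXO target, fell 1.68-fold. The immediate early genes JUN (2.35-fold) and JUND (2.03-fold) fell, as did TNFAIP3 (1.89-fold), an inhibitor of NF-kB signalling, while NFKB1 rose 2.39-fold. The autophagy gene WIPI1 fell 1.72-fold and the proton pump gene ATP6V0D1 rose 1.57-fold. Without control replicate 1 WIPI1, ATP6V0D1, JUND, ICAM3, CXCR4, CCNG2 and AKT2 missed the threshold (adjusted p of 0.054 to 0.18), and without control replicate 2 ATP6V0D1, NFKB1, CCNG2 and AKT2 did (0.054 to 0.096).

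Chromosome Y transcripts were higher in MLXIP-KO cells (12 of 23 genes). An exchange of arrays between the groups is argued against, since 0 MLXIP-KO arrays were out of place for MLXIP, each lying below both control arrays. Admixed T and NK, myeloid, erythroid or kidney cells in the MLXIP-KO arrays are argued against by their markers, since the highest median of these lists was -0.0266. The test asked only for a rise in MLXIP-KO cells. Admixed cells in the control arrays, lineages outside these lists and cells of the same lineage stay untested. Whether the groups are populations that also differ in other chromosome segments cannot be told apart from the knockout. The test ordered the brighter 50% of genes (9193 genes), and 1 stretch, ELOVL2 to H2AC17 (79 of these genes, 122 with the dimmer ones, median of the 79 -0.25), passed the limit set from 1000 shuffled orders, as the test required. But it is the histone gene cluster, and without histone genes 0 windows of 40 genes passed (largest 0.296, limit 0.300). That limit was set with histone genes included. The 40 brighter non-histone genes inside the stretch had a median of -0.12, against 0.05 for all ordered genes. The 25 histone genes outside the stretch had a median of -0.17, against -0.24 for the 48 inside. Whether the segment itself shifted stays open. Shorter segments and segments seen only in the dimmer genes are not covered, and a difference between the cell populations may account for part of the 1786 calls.

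KIT and PDGFRA neighbour each other, near LNX1 and CHIC2, in GRCh38.p14, and LNX1 (log2 change -1.66) and CHIC2 (-0.60) were also lower, while KDR (-0.20) beyond KIT and GSX2 (-0.03) between CHIC2 and PDGFRA did not pass. PDGFRA missed the threshold with robust estimation (adjusted p = 0.24), with every probe set on its own (0.10), and without control replicate 1 (0.057) or 2 (0.067). NRG3 likewise lies near SH2D4B (-1.37) and TSPAN14 (-0.46), both lower. These neighbours were chosen after their values were seen. Across the genome outside chromosome Y, without histone genes, 155 neighbouring pairs were called in the same direction (101 higher, 54 lower), above the largest count of 121 in 1000 shuffled orders. The shuffled orders mixed genes of all signal levels, so they do not allow for called genes lying together because their levels are alike. Neighbouring paralogs, overlapping genes and shared promoters may give such pairs too and were not separated. The count therefore does not decide whether whole regions changed. Near TFDP1, CUL4A was at 0.52 and LAMP1 at 0.26, neither past the threshold. Other genes around TFDP1 are not given here, so these values do not settle whether its neighbourhood changed.

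The rise of ribosome biogenesis and mitochondrial ribosome genes was set against 3 technical explanations. A dependence of the fold change on signal level is argued against, since both medians lay above all of 10000 lists matched on mean level (percentile 100). The single array MLXIP-KO replicate 3, with the widest spread, is argued against as well, since without it the 2 medians kept at least 0.897 of their size. Shifted chromosome segments cannot be told apart by the test made, because 0 members lay in the stretch and the ratio of 1 was fixed by that. The lower MLXIP transcript level, which the design names, and a difference between the cell populations stay open as untested explanations.

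The fall of ZNF667-AS1 and of other zinc finger transcripts prompted the hypothesis that the ZNF family as a whole was lower. The median of 494 ZNF genes, -0.03, lay at percentile 24.7 of matched lists, so no family-wide shift of the median was found. Of the 494, 11 rose and 26 fell, whereas of all 18417 genes 1148 rose and 638 fell. Whether this lean of the calls towards falls exceeds chance was not tested.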
